A study of Homo sapiens with 44 samples.

How the data were processed

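RNA of 4 human acute myeloid leukemia (AML) cell lines, HL-60, THP-1, MOLM-14 and U937, was measured on Affymetrix high-throughput human genome arrays after lentiviral RNA interference. Per the labels, each line was infected with a scrambled control hairpin (3 arrays), with 2 hairpins against GSK3A (2 arrays each) or with 2 hairpins against GSK3B (2 arrays each), which gives 11 arrays per line and 44 in all. Cells grew in RPMI medium, selection with puromycin at 1 µg per mL began 48 h after infection, RNA was taken with a column kit 48 h later, and biotin-labelled cRNA was hybridized. The labels call the replicates biological, and nothing else is given about separate cultures or infections. If replicates are technical, the p-values measure only the spread between these arrays.

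The deposited values are intensity summaries of 22277 probe sets on a linear scale, already normalized between arrays by the authors. The submitters' processing notes name both RMA and MAS5. Which of these gave the deposited table, and the versions and settings, are not given in the sources used here. Deposited intensity ran from 3.40 to 12933, the array medians from 18.95 to 22.9 and the array upper quartiles from 139 to 151. The number of arrays limits the precision of every value. All 44 data columns matched a labelled sample.

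Intensities were turned into log2(value + 16). The array medians then spanned 0.154 on the log2 scale, more than the limit of 0.1 set in advance, so the arrays were quantile-normalized. The pseudocount of 16 makes log2 changes of dim genes smaller than the changes in intensity. Of the probe sets, 62 are control probe sets, 19724 name 1 gene, 568 name several genes and 1923 name none. Current symbols came through the Entrez gene identifier for 19707 probe sets, and a human gene table served for names only. For the 4505 genes with more than 1 probe set, the probe set with the highest mean over all arrays was kept, which left 12165 genes. Probe sets with several genes or none were not used in the gene counts.

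The means of all 20 groups (cell line and construct) were fitted with limma 3.58.1 in R 4.3.3, which leaves 24 residual degrees of freedom and 1 shared estimate of the spread per gene. That spread lies between replicate arrays of a line and hairpin, so p-values for a target do not measure the spread between its hairpins. The GSK3A change is the mean of its hairpins minus the control, averaged over the 4 lines, and the GSK3B change was taken in the same way. The difference between the targets uses no control array. Each hairpin was also tested over the 4 lines and each target within each line. Differences between lines were tested with a moderated F-test. All gene tests were two-sided, and p-values were Benjamini-Hochberg adjusted with a threshold of 0.05. An error after ± is a standard error of the fit unless named SD. Hairpins of both targets share the control arrays, so correlations stand beside a simulated chance value and beside values with the controls split between the hairpins. Overlaps stand only beside the number that independent lists would share, which makes no allowance for the shared controls.

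The 22 gene lists, with 616 different genes of which 539 were measured, were written from general knowledge, not from these samples. They cover mature myeloid genes, stem and progenitor genes, primary granule genes, Wnt and beta-catenin targets, the cell cycle, MYC and ribosome biogenesis, p53 targets, interferon response, ATF4 and endoplasmic reticulum stress, cholesterol and fatty acid synthesis, glycogen metabolism, NRF2 targets, NF-kB and inflammation, oxidative phosphorylation, apoptosis regulators, lysosome and autophagy, hypoxia and glycolysis, and markers of erythroid, megakaryocyte, T and NK, B, and epithelial and stromal cells. Lists were tested with camera of limma with a preset correlation between genes of 0.01, and again with an estimated correlation. The estimated correlation in the fits by plate columns was added after the results were seen. P-values were adjusted over the lists of a contrast. Fry, which tests only whether a list moves to one side, was run as an alternative.

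Named genes follow a rule. It takes GSK3A and GSK3B, and for each contrast over the lines the 10 rising and 10 falling genes with the largest change that passed the test with 1 sign in every hairpin and line. It also takes up to 4 members per list with the smallest adjusted p. For each target in each line it takes the 3 rising and 3 falling genes with the largest change and 1 sign in both hairpins, and for each test between lines the 5 genes with the smallest adjusted p. A fixed set of AXIN2, LEF1, MYC, CD14, ITGAM, MPO, HOXA9 and MEIS1 completes it. AXIN2 and HOXA9 had no probe set that names them alone.

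The comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. Alternatives tried were median scaling or cyclic loess in place of quantile normalization, leaving out dim genes (below the 40th percentile of mean level), every probe set, trended and robust variances, only the arrays of the groups compared, a replicate block, a block for plate columns, a random block for cell line and construct (statmod 1.5.0), each cell line left out, a fold threshold of 1.5, and each array left out. By the well names in the labels each line lies side by side on a plate, with controls 1 and 2 and replicate 1 of every hairpin in plate columns 1 to 6, and control 3 and replicate 2 of every hairpin in plate columns 7 to 11. Values with plate columns as a block, and values within each set of columns, therefore stand beside the pooled ones. Tests within columns use cell line and target as groups, so differences between the hairpins of a target enter the spread there.

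The calling was tested on simulated data made from the control means and residual spreads of these arrays. Of 67 genes changed by 1.25-fold in all lines, 94.0% were recovered in the contrast over 4 lines with limma, with 10 calls among unchanged genes. Within HL-60, 68.7% of genes changed by 1.25-fold and 91.0% of those changed by 1.5-fold were recovered. The simulated noise was independent between genes, with the same spread in all lines and no effect of plate columns. These rates therefore do not carry over to arrays with such effects. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The western blots that the labels mention, protein levels and differentiation assays were not analysed here.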

Results

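Gene expression was compared between AML cells with a scrambled control hairpin and cells with a hairpin against GSK3A or GSK3B, the genes of the alpha and beta forms of glycogen synthase kinase 3. This kinase phosphorylates glycogen synthase and beta-catenin, among many other proteins. The lines differ in stage: HL-60 is promyelocytic, THP-1 and MOLM-14 are monocytic with rearranged KMT2A, and U937 is monocytic. There were 12 control arrays, 16 GSK3A hairpin arrays and 16 GSK3B hairpin arrays, with 3, 4 and 4 in each of the 4 lines. The GSK3A hairpins are called hairpin 5 and hairpin 6 and the GSK3B hairpins B-1 and B-2, each with 8 arrays. The question, as far as the study is known, was whether suppression of either paralog moves AML cells toward myeloid differentiation. Array medians of deposited intensity lay between 18.95 and 22.9.

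The targeted transcripts were examined first, as a check of the labels. GSK3B fell with the GSK3B hairpins in every line. Its deposited intensity went from 187 ± 14.5 (SD, n = 3) in HL-60 controls to 45.1 ± 10.4 (SD, n = 4), which is 24.1% of control. In THP-1 it went from 186 ± 8.86 to 87.1 ± 10.8 (46.7%), in MOLM-14 from 158 ± 16.02 to 29.96 ± 7.70 (18.9%), and in U937 from 167 ± 6.00 to 45.2 ± 11.6 (27.1%). All 16 GSK3B hairpin arrays lay between 22.4 and 97.7, below the lowest control array at 140. The log2 change over the lines was −1.56 ± 0.05 (limma, adjusted p = 8.1e-19), with −1.43 ± 0.06 for B-1 and −1.69 ± 0.06 for B-2. With the GSK3A hairpins the GSK3B change was 0.00 ± 0.05 (adjusted p = 0.969).

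The GSK3A transcript moved far less with its own hairpins. On its brighter probe set, deposited intensity went from 54.2 ± 3.21 (SD, n = 3) to 45.4 ± 0.956 (SD, n = 4) in HL-60. It was 37.2 ± 4.64 and 35.9 ± 5.07 in THP-1, 45.9 ± 1.38 and 44.8 ± 1.65 in MOLM-14, and 44.5 ± 4.40 and 41.1 ± 3.90 in U937. The log2 change over the lines was −0.09 ± 0.03 (limma, adjusted p = 0.0176). HL-60 alone passed the test among the lines, at −0.20 (adjusted p = 0.0139), and the change was −0.03 (0.996) in THP-1, −0.03 (0.811) in MOLM-14 and −0.09 (0.460) in U937. Hairpin 5 gave −0.07 ± 0.03 (adjusted p = 0.11) and hairpin 6 −0.10 ± 0.03 (adjusted p = 0.025). Blocked on plate columns, the change over the lines was −0.10 (adjusted p = 0.00381), and within plate columns 1 to 6 and 7 to 11 alone it was −0.08 (0.282) and −0.12 (0.462). The call was lost without HL-60, at −0.05 (adjusted p = 0.376), and on the other probe set, at −0.08 (0.0908). In THP-1, MOLM-14 and U937 the deposited intensity was 96.6%, 97.6% and 92.4% of control on the brighter probe set and 93.6%, 105% and 96.7% on the other, so no clear knockdown of the transcript was seen in these lines. On the brighter probe set, hairpin 6 in THP-1 and MOLM-14 and hairpin 5 in U937 lay below every control array, and the other hairpin did not. Room for a fall was smaller on the other probe set. Its control means of 20.1 to 27.5 lay near the array medians of 18.95 to 22.9. The control means of the brighter probe set were 37.2 to 54.2, and array lower quartiles were 7.57 to 8.28. GSK3B with its own hairpins still read 22.4 to 97.7, against control means of 158 to 187. How low GSK3A would read without its transcript was not tested. The protein blots named in the labels were not analysed here.

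**Figure D1:**
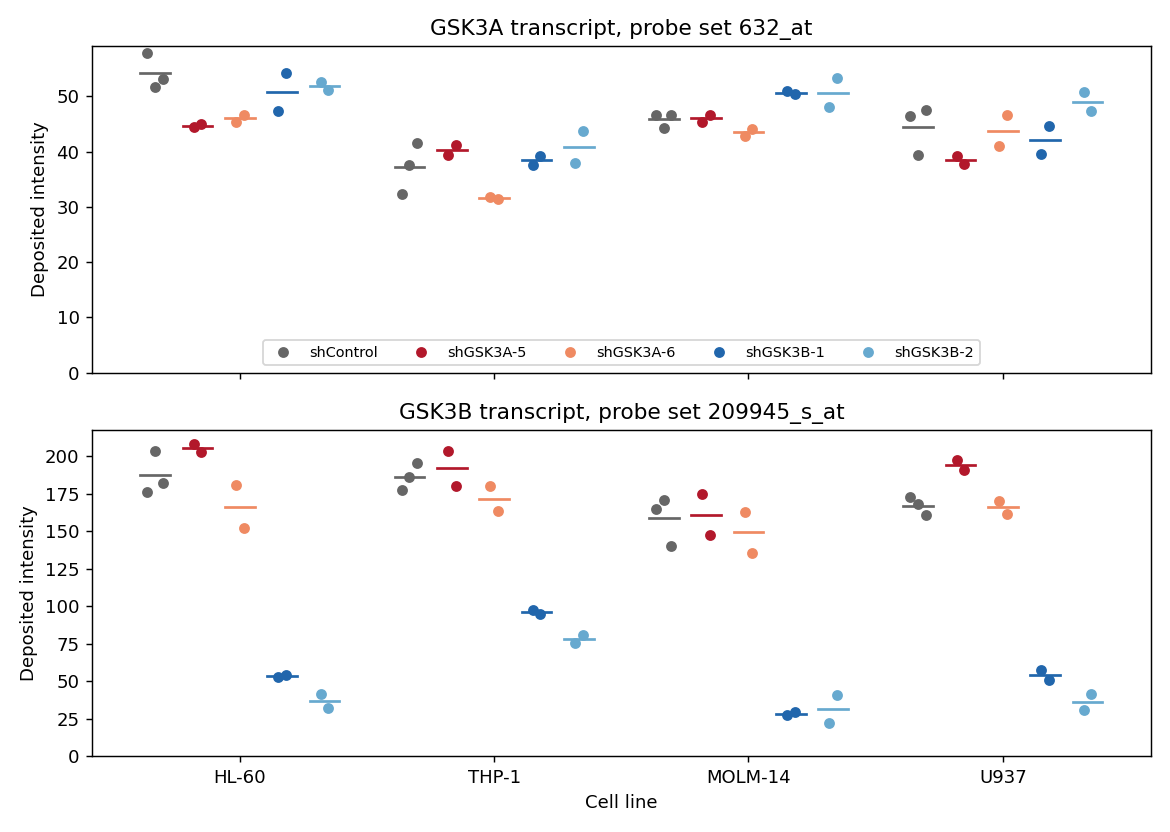
Deposited intensity (linear axis) of GSK3B and of GSK3A (its brighter probe set) in each array, by cell line and hairpin, with group means. GSK3B hairpin arrays lie between 22.4 and 97.7 for GSK3B, and GSK3A arrays of the GSK3A hairpins overlap the controls except in HL-60.

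With the GSK3A hairpins, RNASE6, CHI3L1 and CD86 had the largest rises and MTHFD2 the largest fall among the genes that changed in 1 direction with both hairpins and in all 4 lines. RNASE6, a ribonuclease of myeloid cells, rose 1.98-fold (log2 0.99 ± 0.07, adjusted p = 2.0e-11), and in U937 its mean normalized intensity went from 19.3 ± 4.96 (SD, n = 3) to 53.2 with hairpin 5 and 115 with hairpin 6. CHI3L1, a chitinase-like protein that macrophages secrete, rose by log2 0.95 ± 0.19 (adjusted p = 4.5e-04), and CD86, a costimulatory molecule of monocytes and dendritic cells, by 0.91 ± 0.14 (1.1e-05). The myeloid receptor TREM1 rose by 0.87 ± 0.13 (8.0e-06), the Fc receptor FCGR2B by 0.81 ± 0.17 (7.7e-04) and LY96, the partner of TLR4, by 0.78 ± 0.11 (4.2e-06). MTHFD2, a mitochondrial enzyme of one-carbon metabolism, decreased 1.89-fold (log2 −0.92 ± 0.07, adjusted p = 4.1e-10). In HL-60 its normalized intensity went from 1414 ± 64.4 (SD, n = 3) to 524 and 745 with hairpins 5 and 6.

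Other genes that rose by log2 0.78 to 0.86 were the lysosomal sulfatase IDS (0.86 ± 0.08, adjusted p = 1.3e-08), the secreted adenosine deaminase ADA2 (0.82 ± 0.16), the tubulin TUBA1A (0.81 ± 0.16) and the pattern recognition protein PTX3 (0.78 ± 0.09). Genes that fell included the neuropeptide GAL (−0.81 ± 0.10), the actin-binding calponin CNN2 (−0.81 ± 0.04), the Rap exchange factor RASGRP2 (−0.72 ± 0.06) and RRN3 (−0.64 ± 0.04), a factor of ribosomal RNA transcription. The copper chaperone ATOX1 (−0.62 ± 0.07), LZTFL1 (−0.58 ± 0.05), SEL1L3 (−0.58 ± 0.09), the replication factor MCM10 (−0.58 ± 0.11) and TSN (−0.57 ± 0.03) also fell. All of these had the same sign with both hairpins and in each of the 4 lines. Some rested mostly on 1 hairpin: CNN2 changed by −1.53 with hairpin 5 and by −0.09 with hairpin 6, RRN3 by −0.23 and −1.05, and TREM1 by 1.53 and 0.21. Among the genes fixed in advance, CD14 rose by 0.33 ± 0.03 (adjusted p = 1.0e-08), ITGAM by 0.39 ± 0.06 (1.7e-05), MYC fell by 0.44 ± 0.10 (0.00232) and MPO by 0.39 ± 0.05 (4.5e-06). These are means over the lines. The CD14 rise came mostly from HL-60, and the MPO fall mostly from MOLM-14. LEF1 (0.02 ± 0.03) and MEIS1 (−0.04 ± 0.07) did not pass.

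Of 12165 genes, 1320 rose and 1240 fell (limma), and 1600 of these 2560 had the same sign in every hairpin and line. A change of at least 1.5-fold was reached by 32 rising and 6 falling genes. With plate columns as a block 4041 genes passed, and within plate columns 1 to 6 and 7 to 11 alone 1405 and 42 passed. The count was 1265 with cell line and construct as a random block and 1593 without HL-60.

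Mature myeloid genes, such as receptors and enzymes of monocytes and granulocytes, moved up together with the GSK3A hairpins. Of 45 measured, 28 rose, 0 fell and 17 did not pass, and 31 rose when adjusted over the list alone. TYROBP, an adaptor of myeloid receptors, rose by log2 0.59 ± 0.05 (adjusted p = 1.5e-09), the lysosomal fucosidase FUCA1 by 0.65 ± 0.07 (9.1e-08), and AIF1, a calcium-binding protein of macrophages, by 0.47 ± 0.05 (4.8e-08). The calprotectin genes S100A9 and S100A8, which were looked up after the values were seen, did not pass, at −0.19 and −0.14. S100A8 also differed between plate columns 7 to 11 and 1 to 6, by 1.51 in MOLM-14 and −1.90 in U937. The list median was 0.25 (camera, adjusted p = 6.0e-14), and the call held with an estimated correlation (0.00176). The median was 0.25 with plate columns as a block, 0.30 within columns 1 to 6 and 0.21 within columns 7 to 11.

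Lysosome and autophagy genes that TFEB controls rose as well, with 21 of 32 higher, 2 lower (LAMP2 −0.26 and CTSF −0.13) and 9 not past the test. Adjusted over the list alone 22 rose and 2 fell. WIPI1, which acts in autophagosome formation, rose by log2 0.49 ± 0.06 (adjusted p = 5.0e-07), the proton pump subunits ATP6V1A and ATP6V1H by 0.44 ± 0.05 and 0.23 ± 0.03, and TFEB itself by 0.38 ± 0.05. The median was 0.19 (camera, adjusted p = 7.1e-08, and 0.00201 with an estimated correlation). It was 0.19 in the blocked fit, 0.18 in columns 1 to 6 and 0.19 in columns 7 to 11.

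Genes of MYC and ribosome biogenesis fell: 19 of 25 were lower and 0 higher, and 22 were lower when adjusted over the list alone. Among them were the nucleolar proteins NCL (−0.17 ± 0.03) and NOLC1 (−0.16 ± 0.03), the polyamine enzyme ODC1 (−0.16 ± 0.03, adjusted p = 3.3e-05) and the nucleoside kinase NME1 (−0.19 ± 0.04). The median was −0.16 (camera, adjusted p = 6.1e-10, and 0.0137 with an estimated correlation), −0.16 when blocked, −0.17 in columns 1 to 6 and −0.12 in columns 7 to 11. Of 39 cell cycle genes 15 fell and 0 rose, 18 fell when adjusted over the list alone, and the median was −0.20 (camera, adjusted p = 4.8e-09). That call was lost at adjusted p = 0.581 with an estimated correlation. Among the members, the replication licensing genes MCM6, MCM4 and CDC6 changed by −0.37 ± 0.05, −0.55 ± 0.10 and −0.53 ± 0.10, and CDC45 by −0.40 ± 0.08. The median was −0.19 when blocked, −0.20 in columns 1 to 6 and −0.17 in columns 7 to 11. The cell cycle mean over the lines rested mostly on MOLM-14, with a median of −0.96 and 37 members lower there. The medians in HL-60, THP-1 and U937 were 0.10, 0.05 and −0.12, with 0 members lower.

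Interferon response genes rose in 17 of 38 cases, and 1 (USP18) fell, with the same counts adjusted over the list alone. The proteasome subunit PSMB9 rose by log2 0.65 ± 0.06 (adjusted p = 3.7e-09), MX2 by 0.47 ± 0.05, TRIM22 by 0.49 ± 0.06 and IRF9 by 0.40 ± 0.06. The median of 0.11 (camera, adjusted p = 1.1e-06) was 0.13 when blocked, 0.15 in columns 1 to 6 and 0.11 in columns 7 to 11. The call was lost at adjusted p = 0.0532 with an estimated correlation. With hairpin 6 on its own the list was not called, with a median of 0.04, 7 members higher and 4 lower (camera, 0.206). By line, U937 was called (median 0.20, 9 higher; camera, adjusted p = 3.8e-09, and 0.0144 with an estimated correlation). HL-60 (0.13; camera, 5.9e-05) and MOLM-14 (0.09; 0.00387) lost their calls at adjusted p = 0.115 and 0.312 with an estimated correlation. THP-1 was not called (0.05; 0.416). Of 20 p53 targets 6 rose, with ZMAT3 at 0.35 ± 0.04, CDKN1A at 0.37 ± 0.07, BAX at 0.23 ± 0.05 and TNFRSF10B at 0.28 ± 0.07, and TRIAP1 fell by 0.11. Adjusted over the list alone 8 rose and 1 fell. The p53 mean over the lines rested mostly on MOLM-14, with a median of 0.29 and 13 members higher there. In HL-60, THP-1 and U937 the medians were −0.003, −0.001 and 0.006, with 2, 0 and 1 members higher and 1, 0 and 1 lower. The median of 0.07 (camera, adjusted p = 0.0053) was 0.07 when blocked, 0.08 in columns 1 to 6 and 0.05 in columns 7 to 11 (camera, 0.06, not called), and the call was lost at adjusted p = 0.0566 with an estimated correlation.

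The other 16 lists were not called with the GSK3A hairpins in the pooled fit. Blocked on plate columns, camera with the preset correlation called primary granule genes lower (median −0.11, adjusted p = 0.0342) and NRF2 targets (0.07, 0.0224) and NF-kB genes (0.02, 0.0175) higher. These calls were lost at adjusted p = 0.392, 0.106 and 0.0504 with an estimated correlation in that fit. NRF2 targets were also called within columns 1 to 6 (0.0338, lost at adjusted p = 0.622 with an estimated correlation), and oxidative phosphorylation was called lower within columns 7 to 11 (0.0132, lost at 0.618). Of the lists called in the pooled fit, mature myeloid, lysosome and MYC genes held in the blocked fit with an estimated correlation (adjusted p = 0.00204, 0.0263 and 8.0e-04), and cell cycle, interferon and p53 genes did not (0.106, 0.116 and 0.106). Within columns 1 to 6 alone, with an estimated correlation, p53 targets were called (0.0449), and mature myeloid (0.262), lysosome (0.129) and MYC genes (0.129) were not. Within columns 7 to 11 no list was called in this way (mature myeloid 0.464, lysosome 0.214, MYC 0.464). Of 23 stem and progenitor genes 3 rose (PBX3 0.30 and LMO2 0.18 among them) and 3 fell (MYB −0.34 and GATA2 −0.17 among them), with camera at adjusted p = 0.367. Of 13 primary granule genes, RNASE2 rose (0.13) and 3 fell, with MPO at −0.39, PRTN3 at −0.43 and DEFA4 at −0.11 (camera, adjusted p = 0.307). Of 21 Wnt and beta-catenin targets 3 rose and 2 fell, including PPARD (0.47), TCF7L2 (0.24), CCND2 (−0.28) and MYC (−0.44), with camera at 0.581. The NF-kB list had 7 of 29 higher, with TNFAIP2 at 0.53, BCL2A1 at 0.42 and CCL4 at 0.17 (camera, 0.0741). Apoptosis regulators went both ways, with 9 of 22 higher and 4 lower, among them CASP8 (0.44), BCL2L2 (0.41), TNFSF10 (0.32) and BIK (−0.40), with camera at 0.166.

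Few members of the metabolic lists passed in the mean of both hairpins. The ATF4 list had 2 of 29 higher and 4 lower, with the amino acid transporters SLC7A5 (−0.34) and SLC1A5 (−0.33) and with XBP1 (−0.39) (camera, adjusted p = 0.767). Hypoxia and glycolysis had 4 of 28 higher and 5 lower, with SLC2A3 at 0.49, BNIP3L at 0.49, PFKFB3 at 0.31 and ADM at −0.28 (0.746). Cholesterol synthesis had 2 of 24 higher (ELOVL6 0.18, SC5D 0.15) and ACACA lower (−0.17) (0.497), glycogen metabolism 2 of 18 higher (PYGB 0.19, GYG1 0.15) (0.581), and NRF2 targets 3 of 20 higher (SLC7A11 0.34, ABCC1 0.17, TKT 0.15) (0.166). Oxidative phosphorylation had 2 of 34 higher and 5 lower (0.307). The hairpins parted in some of these lists. Cholesterol synthesis had a median of −0.16 and 4 members lower with hairpin 6 (camera, 8.1e-04, lost at adjusted p = 0.549 with an estimated correlation) and a median of 0.05 with 4 higher and 1 lower with hairpin 5 (0.191). ATF4 targets had 0 higher and 4 lower with hairpin 6 (0.0133, lost at adjusted p = 0.664 with an estimated correlation) and 9 higher and 3 lower with hairpin 5 (0.174). NRF2 targets were called higher with hairpin 5 (6 higher, 0.0168, lost at adjusted p = 0.380 with an estimated correlation) and not with hairpin 6 (0.984), and so were NF-kB genes (10 higher, 0.00132, lost at adjusted p = 0.0772 with an estimated correlation, and 0.968 with hairpin 6). Markers of other cells barely moved: 0 of 14 erythroid (camera, adjusted p = 0.997), 1 of 15 megakaryocyte (NFE2 −0.26, 0.965), 1 of 18 T and NK cell (CD247 −0.06, 0.638), 0 of 14 B cell (0.831) and 1 of 18 epithelial and stromal genes (PECAM1 0.34, 0.638) passed.

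Both GSK3A hairpins moved the mature myeloid list up, hairpin 5 by a median of 0.36 with 29 members higher (camera, adjusted p = 8.9e-15, and 0.00123 with an estimated correlation) and hairpin 6 by 0.13 with 17 higher (2.3e-06 and 0.0353). Hairpin 5 changed 1401 genes up and 1290 down, and hairpin 6 changed 1070 up and 959 down. Of these, 527 rose and 414 fell with both hairpins, 151 moved in opposite directions, and independent lists would share 123 and 102. The hairpins share their control arrays, for which the values for independent lists make no allowance. Over genes, which are not independent replicates, their changes had r = 0.444, against 0.399 in simulations with no change. With the controls split between the hairpins the median r was 0.378 (0.281 to 0.429), and their covariance was 0.0108 against 0.00140 in simulations. A fit with plate columns as a block gave 1784 genes that moved the same way with both. The hairpins also differed from each other in 2043 genes. The interferon list rose by a median of 0.19 with hairpin 5 (21 higher, 1 lower) and was not called with hairpin 6, and its difference between the hairpins was called by camera (adjusted p = 3.1e-08) but not with an estimated correlation (0.067).

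**Figure D2:**
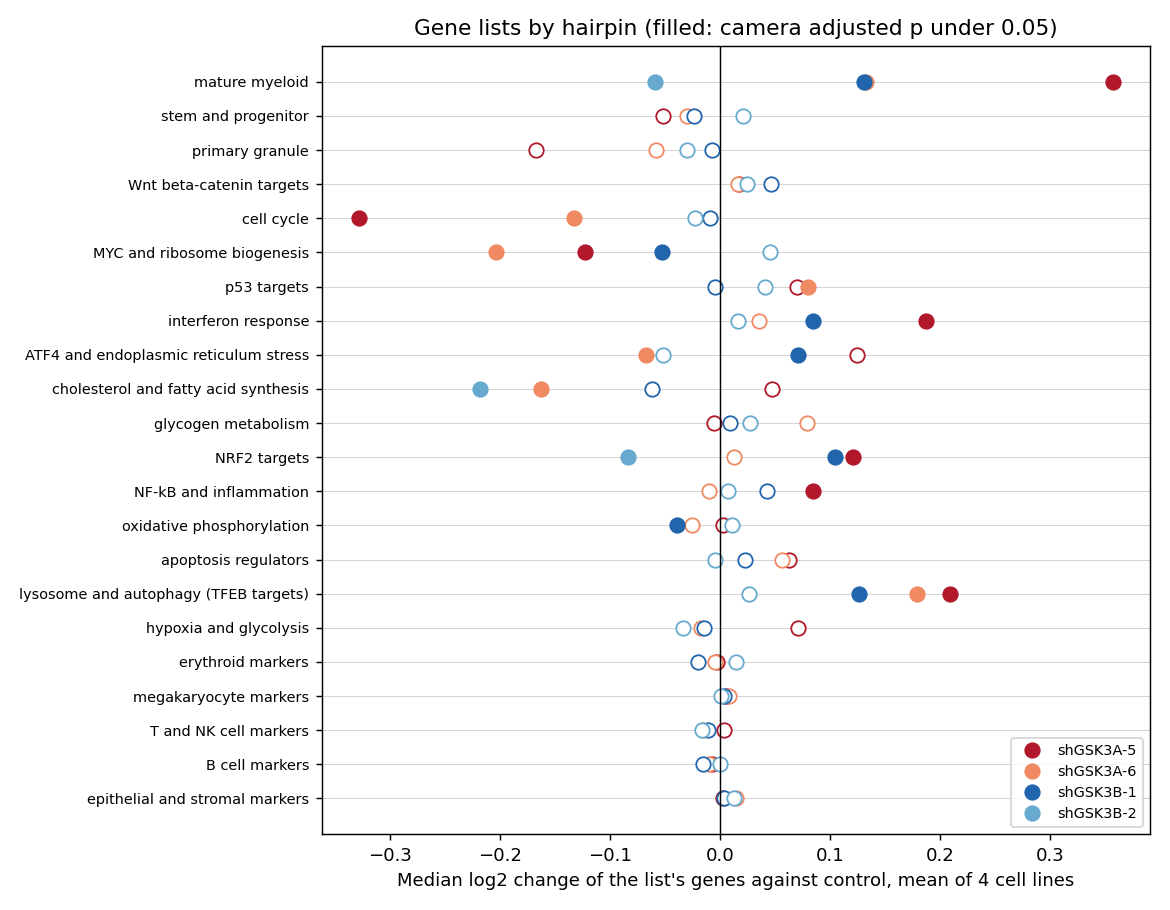
Median log2 change over the members of gene lists for each of the 4 hairpins against control, mean of the 4 lines. Mature myeloid genes lie at 0.36 and 0.13 with GSK3A hairpins 5 and 6, at 0.13 with GSK3B hairpin B-1 and at −0.06 with B-2.

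The genes with the largest changes under the GSK3A hairpins differed in part between the lines, while MTHFD2 was among the largest falls in HL-60 and THP-1 and CNN2 in U937 and THP-1. In HL-60 the innate immune genes PTX3 (log2 1.73 ± 0.18, adjusted p = 1.3e-07) and TREM1 (1.61 ± 0.25) and the haptoglobin gene HP (1.47 ± 0.13) rose most, and the granule protease CTSG (−1.29 ± 0.32), MTHFD2 (−1.16 ± 0.14) and TNFAIP6 (−1.08 ± 0.06) fell most. CD14, the monocyte coreceptor for endotoxin, went from a normalized intensity of 263 ± 8.94 (SD, n = 3) in HL-60 controls to 1081 ± 72.4 (SD, n = 2) with hairpin 5 and 363 ± 15.4 (SD, n = 2) with hairpin 6. Its log2 change was 1.21 ± 0.06 in HL-60 and 0.09, −0.00 and 0.03 in THP-1, MOLM-14 and U937 (interaction test, adjusted p = 1.3e-09). In U937, FCGR2B (1.76 ± 0.34, adjusted p = 0.00149), LY96 (1.72 ± 0.21) and CHI3L1 (1.72 ± 0.38) rose most, and DOCK9 (−1.05 ± 0.16), GAL (−0.90 ± 0.19) and CNN2 (−0.85 ± 0.08) fell most. In THP-1, RNASE6 (0.93 ± 0.13, adjusted p = 9.0e-05), the receptor kinase AXL (0.89 ± 0.20) and CADM1 (0.87 ± 0.15) rose, and ATOX1 (−0.68 ± 0.13), CNN2 (−0.62 ± 0.08) and MTHFD2 (−0.55 ± 0.14) fell.

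MOLM-14 stood apart in the cell cycle. There 37 of 39 cell cycle genes fell and 0 rose, with a median of −0.96 (camera, adjusted p = 7.5e-35), among them MCM4 (−1.43 ± 0.20), CDC6 (−1.39), CDC45 (−1.32) and MCM6 (−1.02). The median was −1.07 within columns 1 to 6 and −0.94 within columns 7 to 11. Between these sets of columns the log2 ratio of 3' to 5' signal of actin and GAPDH control probe sets, a sign of RNA quality, differed by 1.10 ± 0.153 in MOLM-14. The cell cycle call was lost at adjusted p = 0.0815 with an estimated correlation. The difference from the mean of the other 3 lines had a median of −1.01, with 34 members lower (camera, adjusted p = 2.6e-46, and 0.0429 with an estimated correlation). The cell cycle medians in HL-60, THP-1 and U937 were 0.10, 0.05 and −0.12. Camera called U937 alone among these (adjusted p = 0.0382), with 0 members called, and that call was lost at adjusted p = 0.928 with an estimated correlation. Between columns 7 to 11 and columns 1 to 6 the list itself differed by a median of −0.64 in U937, with 38 members lower and 0 higher. In MOLM-14 that median was 0.15, with 17 higher and 0 lower. Blocked on plate columns, camera with the preset correlation did not call U937 (0.423) and called THP-1 higher (0.0427). THP-1 had 0.943 with an estimated correlation in the pooled fit. The cyclin-dependent kinase phosphatase CDKN3 (−1.57 ± 0.23) and MCM10 (−1.56 ± 0.22) fell most in MOLM-14, and the metalloprotease MMP2 (1.61 ± 0.21), IDS (1.45 ± 0.17) and the p53 target ZMAT3 (1.38 ± 0.08, adjusted p = 7.1e-12) rose most. Of 20 p53 targets 13 rose in MOLM-14, with CDKN1A at 0.70 and BAX at 0.57, and the median was 0.29 (camera, adjusted p = 5.4e-10, and 1.3e-04 with an estimated correlation). The difference of that list from the other 3 lines held with an estimated correlation (adjusted p = 4.7e-05). HL-60, THP-1 and U937 were not called for it.

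**Figure D3:**
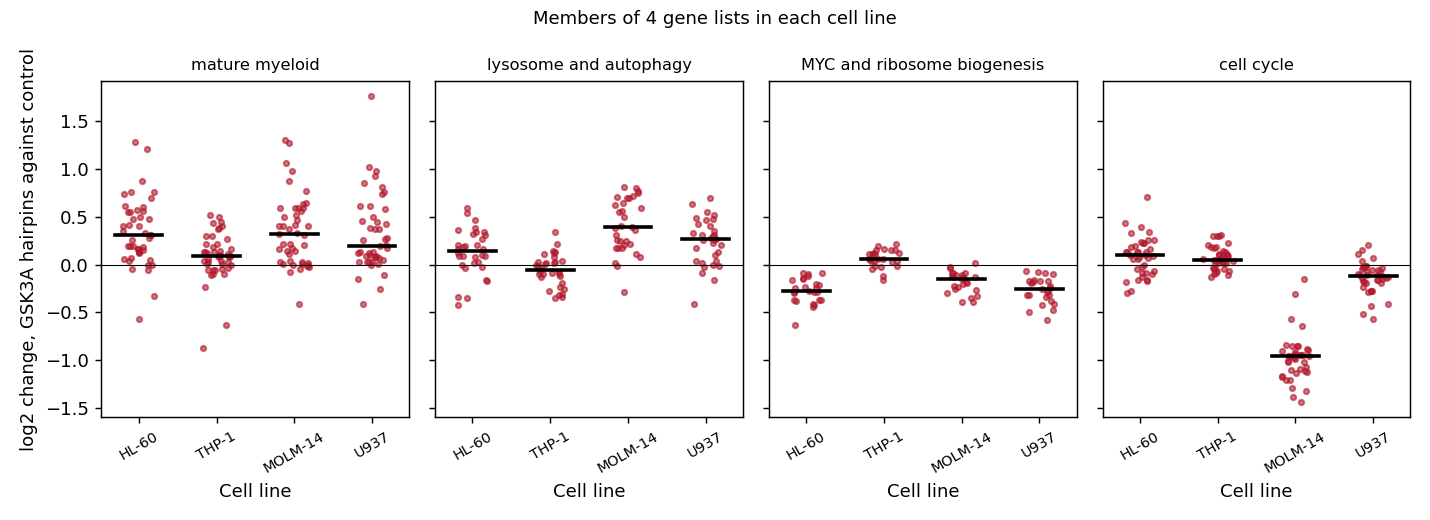
Log2 change with GSK3A hairpins (mean of both) for each measured member of gene lists, 1 point per gene, in each of the 4 lines, with the median. Cell cycle members lie around a median of −0.96 in MOLM-14 and around 0.10, 0.05 and −0.12 in HL-60, THP-1 and U937.

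Mature myeloid genes rose in 18 of 45 cases in HL-60 (1 fell), in 17 in MOLM-14, in 14 in U937 and in 3 in THP-1, with list medians of 0.31, 0.32, 0.19 and 0.09. The camera calls in HL-60, MOLM-14 and U937 held with an estimated correlation (adjusted p = 0.00378, 0.0121 and 0.00805), and that in THP-1 (0.0117) was lost at adjusted p = 0.624 with an estimated correlation. THP-1 lay below the other 3 lines by a median of −0.19 for this list (0.0454 with an estimated correlation) and by −0.28 for the lysosome list (7.8e-05), and above them by 0.31 for the MYC and ribosome list (0.00112). Lysosome genes rose in 21 of 32 cases in MOLM-14 (median 0.39), in 10 in U937 (0.26), in 5 in HL-60 (0.14) and in 1 in THP-1 (−0.05, not called), and 2 fell in HL-60 and 1 in MOLM-14. The first pair of these calls held with an estimated correlation (adjusted p = 1.3e-04 and 0.00108) and HL-60 did not (0.115). Within columns 1 to 6 and 7 to 11 the mature myeloid medians were 0.29 and 0.30 in HL-60, 0.10 and 0.07 in THP-1, 0.41 and 0.22 in MOLM-14, and 0.21 and 0.22 in U937. MYC and ribosome genes fell in 10 of 25 cases in HL-60, 9 in U937, 6 in MOLM-14 and 0 in THP-1, with medians of −0.27, −0.25, −0.15 and 0.06. The list differences between lines and between hairpins were tested after the values were seen.

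In HL-60 493 genes rose and 604 fell, in THP-1 149 and 96, in MOLM-14 1011 and 927, and in U937 442 and 376 (limma, 4 arrays against 3). These counts share an estimate of the spread over all lines. Replicates in different columns differed by 0.109 to 0.122 in HL-60 and 0.0977 to 0.132 in THP-1. In MOLM-14 and U937 they differed by 0.219 to 0.305 and 0.235 to 0.286. With only the arrays compared in each line, HL-60 had the most genes and U937 the fewest, so these counts do not rank the lines. Genes that were called higher in all 4 lines numbered 24 and lower 29, where independent lists would share 0.0182 and 0.0112. Of the falling genes, NCK2 (−0.68 and 0.17), NDUFC1 (0.05 and −0.90) and PDS5A (−0.62 and 0.05) had opposite signs with hairpins 5 and 6. Others rested mostly on 1 hairpin, such as MED21 (−0.03 and −1.03), while MTHFD2 (−1.07 and −0.78) fell with both. All 24 rising genes rose with both hairpins. Every line received the same hairpins, so an effect of 1 hairpin outside its target can recur in all lines. Independent lists make no allowance for that. Called in exactly 1 line were 1019 genes higher and 1062 lower, and 38 genes went in opposite directions in a pair of lines. The response differed between lines for 953 genes by the interaction test. Blocked on plate columns, the counts were 2418, 909, 3391 and 1941 in the lines and 3033 for the interaction. Within columns 1 to 6 they were 119, 23, 1161 and 147, with 230 for the interaction, and within columns 7 to 11 they were 4, 4, 52 and 2, with 0 for the interaction (limma, 599 at an unadjusted p under 0.05). Leaving out 1 array moved the THP-1 count of 245 to 127, 121 and 143 without controls 1, 2 and 3, to 155 and 144 without replicates 1 and 2 of hairpin 5, and to 145 without replicate 2 of hairpin 6. It moved the U937 count of 818 to 400 without control 2, 416 without control 1 and 1200 without control 3.

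**Figure D4:**
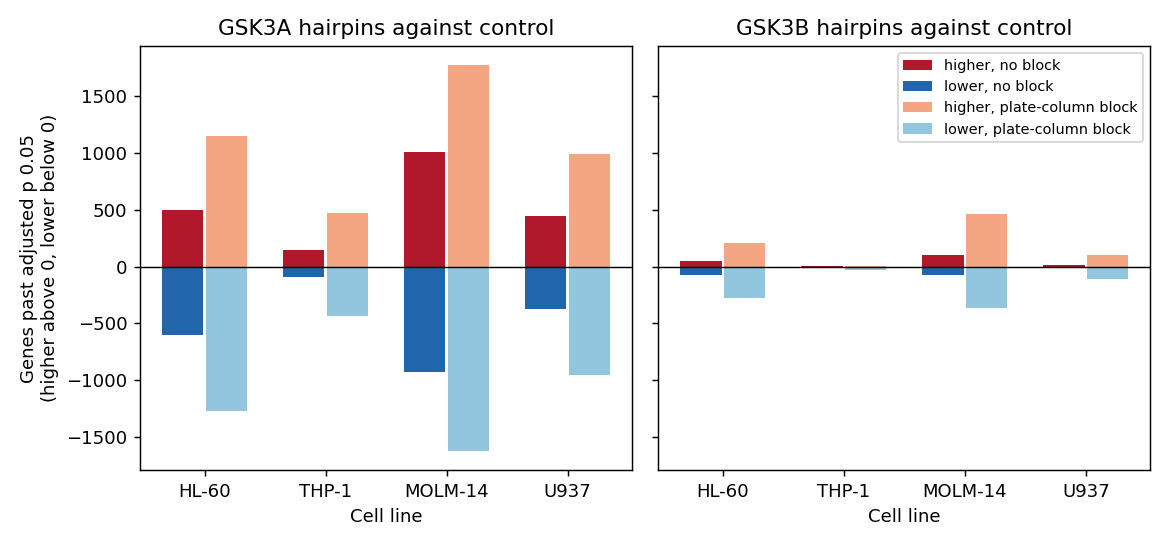
Number of genes with adjusted p under 0.05 (limma), higher and lower, for GSK3A and GSK3B hairpins in each of the 4 lines. The GSK3A counts run from 245 in THP-1 to 1938 in MOLM-14 and the GSK3B counts from 6 in THP-1 to 175 in MOLM-14. The fit shares an estimate of the spread over lines of unequal spread, so the counts do not rank the lines.

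With the GSK3B hairpins fewer genes changed, and GSK3B itself showed the largest fall. DYNLRB1, a light chain of the motor protein dynein, rose 1.57-fold (log2 0.65 ± 0.03, adjusted p = 1.3e-13), by 0.90, 0.44, 0.76 and 0.51 in HL-60, THP-1, MOLM-14 and U937. In HL-60 its normalized intensity went from 564 ± 9.61 (SD, n = 3) to 1087 and 1052 with B-1 and B-2. HSD17B10, a mitochondrial dehydrogenase, rose by 0.57 ± 0.06 (7.6e-07), the actin-severing protein GSN by 0.42 ± 0.05 (1.6e-05), the acetyltransferase KAT2B by 0.37 ± 0.05 and the ubiquitin ligase SMURF2 by 0.35 ± 0.06. PTX3 (0.39 ± 0.09), ID2 (0.34 ± 0.08), the cyclin CCNA1 (0.34 ± 0.08), SS18 (0.32 ± 0.06) and GPR18 (0.32 ± 0.07) also rose. DYNLRB1 and HSD17B10 rose at least as much with the GSK3A hairpins, by 0.75 and 0.65, against the same controls.

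BAG2, a cochaperone, fell by 0.61 ± 0.09 (adjusted p = 1.7e-04), the cholesterol transporter STAR by 0.47 ± 0.09, the ubiquitin-conjugating enzyme UBE2N by 0.47 ± 0.07, and IL1RAP, a coreceptor of interleukin 1, by 0.44 ± 0.06 (1.5e-05). Others that fell were TAX1BP1 (−0.43 ± 0.06), C8orf33 (−0.40 ± 0.08), TSPAN3 (−0.40 ± 0.03), the kinase STK26 (−0.39 ± 0.04) and the splicing factor SRSF10 (−0.37 ± 0.04). Most of the falling genes rested on B-2: BAG2 changed by −0.17 with B-1 and −1.04 with B-2, STAR by −0.05 and −0.90, and STK26 by −0.07 and −0.71. IL1RAP was lower with both, at −0.40 and −0.48. MPO, the myeloperoxidase of primary granules, fell by 0.40 ± 0.05 (3.0e-05). CD14 (−0.08 ± 0.03), ITGAM (0.09 ± 0.06), MYC (−0.12 ± 0.10), LEF1 (0.05) and MEIS1 (−0.01) did not pass.

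Of the 12165 genes, 216 rose and 188 fell (limma), 309 of these 404 with the same sign in every hairpin and line, and 1 rising and 2 falling genes changed at least 1.5-fold. With plate columns as a block 1230 genes passed, and within columns 1 to 6 and 7 to 11 alone 27 and 2 passed. The count was 22 with cell line and construct as a random block, 126 without HL-60 and 245 without THP-1.

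Cholesterol and fatty acid synthesis was the list called with the GSK3B hairpins. Of 24 genes, SC5D, a late enzyme of cholesterol synthesis, fell (−0.18, adjusted p = 0.013), and 10 fell when adjusted over the list alone. The median was −0.15 (camera, adjusted p = 2.5e-08), and the call was lost at adjusted p = 0.337 with an estimated correlation. The median was −0.12 with plate columns as a block (camera, 3.1e-10, and adjusted p = 0.0165 with an estimated correlation), −0.14 within columns 1 to 6 (7.8e-07, and 0.644 with an estimated correlation) and −0.06 within columns 7 to 11 (0.0597). It lay at −0.22 with 8 members lower for B-2 (camera, 4.4e-11, and adjusted p = 0.202 with an estimated correlation), and at −0.06 with 1 member higher and 1 lower for B-1, which was not called (0.321). In MOLM-14 and U937 it was −0.22 and −0.25, with 0 members called in either line (camera, 1.0e-07 and 2.0e-11, and adjusted p = 0.344 and 0.28 with an estimated correlation). In these lines the list also lay lower in columns 7 to 11 than in columns 1 to 6. That median was −0.12 in MOLM-14 (2 higher, 9 lower) and −0.49 in U937 (0 higher, 21 lower). Controls lie unevenly over the columns, so the pooled values carry part of that difference. Blocked on plate columns, the camera calls in both lines stayed (6.5e-13 and 9.6e-13). HL-60 and THP-1 were not called, with medians of 0.03 (camera, 0.893, toward lower) and −0.04 (0.322). Blocked on plate columns, camera with the preset correlation called THP-1 lower (0.0335) and did not call HL-60 (0.941). THP-1 had 0.884 with an estimated correlation in the pooled fit. HL-60 lay above the other 3 lines by 0.23 (camera, 5.6e-04, and adjusted p = 0.664 with an estimated correlation).

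Mature myeloid genes showed 1 call of 45 with the GSK3B hairpins, TYROBP at 0.21 ± 0.05 (adjusted p = 0.016; camera for the list, 0.436). The hairpins parted here: with B-1 10 members rose and the median was 0.13 (camera, adjusted p = 6.6e-09, and 0.0101 with an estimated correlation), and with B-2 6 fell and the median was −0.06 (6.9e-04, lost at adjusted p = 0.202 with an estimated correlation). In the test of B-1 minus B-2 17 members were higher and 1 lower, with a median of 0.18 (camera, 1.9e-12, and 0.00346 with an estimated correlation). Lysosome genes had a median of 0.13 with B-1 and 5 members higher (1.1e-05, and 0.0101 with an estimated correlation), and over both hairpins ATP6V0D1 rose (0.27) and NEU1 (−0.18) and ATP6V1A (−0.19) fell (camera, 0.0669).

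No further list was called in the mean of both hairpins and the 4 lines. With B-1 alone camera called interferon genes (median 0.08, adjusted p = 2.5e-04), NRF2 targets (0.10, 8.8e-04) and ATF4 targets (0.07, 0.0123) higher and oxidative phosphorylation (−0.04, 2.5e-04) and MYC genes (−0.05, 7.1e-04) lower. All were lost, at adjusted p = 0.168, 0.232, 0.670, 0.0521 and 0.205 with an estimated correlation. With B-2 alone NRF2 targets were called lower (−0.08, 0.00854, lost at adjusted p = 0.502 with an estimated correlation). In THP-1 interferon genes were called higher (0.10, 1.2e-05, lost at adjusted p = 0.256 with an estimated correlation), and in U937 lysosome genes (0.09, 0.00485, lost at 0.258). In MOLM-14 NRF2 targets (0.09, 0.0169) and lysosome genes (0.09, 0.00849) were called higher and cell cycle genes (−0.11, 8.6e-04) and oxidative phosphorylation (−0.07, 0.00266) lower. These were lost at adjusted p = 0.484, 0.185, 0.723 and 0.185 with an estimated correlation.

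Blocked on plate columns, camera called the lysosome list with the GSK3B hairpins (median 0.05, 9 members higher and 4 lower, adjusted p = 0.0233), and the call was lost at adjusted p = 0.512 with an estimated correlation. Within columns 1 to 6 it called lysosome genes (0.00123) and interferon genes (0.026) higher and cell cycle genes lower (median −0.06, 0.0017), lost at adjusted p = 0.553, 0.799 and 0.799 with an estimated correlation. Within columns 7 to 11 it called oxidative phosphorylation lower (1.1e-04) and cell cycle genes higher (median 0.08, 0.0143), lost at adjusted p = 0.652 and 0.923 with an estimated correlation, so the cell cycle direction did not hold between the sets of columns. Of 21 Wnt and beta-catenin targets ID2 alone rose (camera, adjusted p = 0.0961), and of 18 glycogen genes PPP1R3D (0.21) and GYG1 (0.13) rose (0.353). Oxidative phosphorylation had 4 of 34 lower, with NDUFS1 at −0.17 and CYCS at −0.15 (0.0649). Primary granule genes had RNASE2 (0.22) and DEFA4 (0.18) higher and MPO lower (0.936), and apoptosis regulators HTRA2 (−0.27) and BIK (−0.20) lower (0.397). Single members passed in the interferon list (PSMB9 0.23; 0.0669), the cell cycle (CDC6 −0.37; 0.354), the MYC list (ODC1 −0.16; 0.478) and the NF-kB list (PTX3; 0.478). No member passed among stem and progenitor genes (0.936), p53 targets (0.397), ATF4 targets (0.936), NRF2 targets (0.936), hypoxia and glycolysis (0.34), or erythroid (0.936), megakaryocyte (0.735), T and NK (0.353), B cell (0.566) and epithelial and stromal markers (0.962).

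B-1 changed 297 genes up and 267 down, and B-2 405 up and 358 down. Both raised 43 and lowered 20, where independent lists would share 9.89 and 7.86, and 64 went in opposite directions. The values for independent lists make no allowance for the shared controls. Over genes the changes of B-1 and B-2 had r = 0.0523, below the 0.403 that shared controls gave in simulations with no change. Their covariance was 0.000487 against 0.00142, and with split controls the median r was −0.0623 (−0.229 to 0.0340). They differed from each other in 1337 genes. A fit blocked on plate columns gave 292 genes that moved the same way with both, against 63 in the pooled fit, which became 95 without U937 control 3.

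Within lines, GSK3B hairpins raised 50 and lowered 70 genes in HL-60, 2 and 4 in THP-1, 100 and 75 in MOLM-14, and 10 and 16 in U937 (limma). With the spread shared over lines, these counts do not rank the lines either. DYNLRB1 rose in each line. In HL-60 the eosinophil granule gene PRG2 rose by 0.85 ± 0.06 (adjusted p = 1.0e-09) and HSD17B10 by 0.68 ± 0.12, and UBE2N (−0.57 ± 0.14) and RNF170 (−0.55 ± 0.11) fell. In MOLM-14 MPO fell by 1.42 ± 0.11 (3.3e-09) and the aldehyde dehydrogenase ALDH1A3 by 0.85 ± 0.16, and CSRP3 (0.83 ± 0.18) and GSN (0.72 ± 0.11) rose. In U937 KAT2B (0.49 ± 0.10) and NAGK (0.47 ± 0.08) rose and STK26 (−0.55 ± 0.07) and SPOCK1 (−0.43 ± 0.09) fell. In THP-1 ADGRG6 rose (0.37 ± 0.06) and CEACAM6 (−0.42 ± 0.08) and GABBR2 (−0.38 ± 0.06) fell. Genes with an unadjusted p under 0.05 numbered 387 in THP-1 and 694 in U937.

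The response to GSK3B hairpins differed between lines for 26 genes, among them MPO, which was −1.42 in MOLM-14 and −0.13, −0.10 and 0.05 in HL-60, THP-1 and U937 (interaction test, adjusted p = 2.9e-06). Blocked on plate columns, the counts in HL-60, THP-1, MOLM-14 and U937 were 484, 33, 823 and 218, with 158 for the interaction. Within columns 1 to 6 they were 5, 2, 15 and 2, with 5 for the interaction. Within columns 7 to 11 they were 0, 0, 1 and 0, with 0 for the interaction (limma, with 439, 173, 433, 225 and 202 at an unadjusted p under 0.05). In MOLM-14, replicate 2 of B-2 stood apart in RNA quality. Its log2 ratios of 3' to 5' signal were 1.69 for GAPDH and 2.55 for actin, against 0.77 to 0.97 and 1.56 to 2.07 in the other MOLM-14 arrays of columns 7 to 11. Without it the MOLM-14 count was 125 and the MPO change there −1.46 (adjusted p = 3.7e-08). Leaving out 1 array moved the MOLM-14 count to 69 without control 1, 70 without control 2, 116 without replicate 2 of B-1 and 492 without replicate 1 of B-2. It moved the U937 count to 4 without control 1, 4 without control 2, 17 without replicate 2 of B-1 and 130 without control 3. The THP-1 count went to 3 without control 1 and 11 without replicate 1 of B-2, and the HL-60 count to 74 without control 1. The count of the interaction went to 15 without HL-60 control 1 and to 15 without HL-60 control 3.

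The GSK3A and GSK3B hairpins were compared directly. Apart from GSK3B (1.57 ± 0.04), the genes highest with GSK3A relative to GSK3B hairpins were the costimulatory molecule CD86 (log2 1.06 ± 0.13, adjusted p = 3.2e-07), the chemokine receptor CX3CR1 of monocytes (1.01 ± 0.05, 5.6e-14), FCGR2B (0.95 ± 0.16), TUBA1A (0.93 ± 0.15), TREM1 (0.91 ± 0.12), ADA2 (0.89 ± 0.15), TRAF3IP3 (0.89 ± 0.07), RNASE6 (0.86 ± 0.06) and IDS (0.86 ± 0.08). Lower with GSK3A hairpins were MTHFD2 (−0.90 ± 0.07, 9.5e-11), CNN2 (−0.88 ± 0.03), the adhesion molecule ALCAM (−0.71 ± 0.08), the metallothionein MT2A (−0.66 ± 0.05), RRN3 (−0.66 ± 0.04) and ATOX1 (−0.66 ± 0.06). NETO2 (−0.65 ± 0.05), CDKN3 (−0.62 ± 0.11), the general transcription factor subunit GTF2E2 (−0.59 ± 0.03) and the neurofilament gene NEFH (−0.58 ± 0.04) were lower too. Against control, some of these rested mostly on 1 GSK3A hairpin. With hairpins 5 and 6 CX3CR1 changed by 1.31 and 0.14, CNN2 by −1.53 and −0.09, GTF2E2 by −0.88 and −0.20 and RRN3 by −0.23 and −1.05. Others moved with both, such as MTHFD2 (−1.07 and −0.78), RNASE6 (0.71 and 1.26) and ATOX1 (−0.54 and −0.69). CD14 was 0.41 ± 0.03 higher, ITGAM 0.30 ± 0.06 higher and MYC −0.32 ± 0.10 lower (0.0168), MPO showed 0.01 ± 0.05 (0.955), and GSK3A itself was −0.12 ± 0.03 (6.6e-04).

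Of the 12165 genes, 1297 were higher and 1358 lower with GSK3A hairpins (limma, 16 arrays against 16), 1440 of these 2655 with the same sign for every pair of hairpins and every line, and 35 higher and 9 lower by at least 1.5-fold. The arrays come from only 2 hairpins per target, and the p-values do not measure the spread between hairpins. Hairpins 5 and 6 differed from each other in 2043 genes, and the GSK3B hairpins in 1337. With plate columns as a block 4106 genes passed, and within columns 1 to 6 and 7 to 11 alone 938 and 387 passed. The count was 1473 with cell line and construct as a random block and 1710 without HL-60.

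Mature myeloid genes were higher with GSK3A hairpins in 26 of 45 cases and lower in 0, and in 30 when adjusted over the list alone, with a median of 0.24 (camera, adjusted p = 1.4e-12, and 0.00327 with an estimated correlation). The median was 0.24 when blocked, 0.21 in columns 1 to 6 and 0.24 in columns 7 to 11. Lysosome genes were higher in 14 of 32 cases and lower in 2, and 16 and 3 adjusted over the list alone (median 0.12; camera, 5.4e-05, and 0.0238 with an estimated correlation; 0.12 blocked, 0.11 and 0.11 within columns). MYC and ribosome genes were lower in 16 of 25 cases, and in 17 adjusted over the list alone (median −0.16; 1.4e-08, and 0.026 with an estimated correlation; −0.16 blocked, −0.15 and −0.16 within columns). Cell cycle genes were lower in 16 of 39 cases, and in 22 adjusted over the list alone, with a median of −0.19 (−0.19 blocked, −0.14 and −0.27 within columns). Their camera call (8.6e-08) was lost at adjusted p = 0.605 with an estimated correlation. Against control, the GSK3A hairpins lowered cell cycle genes mostly in MOLM-14, with a median of −0.96 there. It was 0.10, 0.05 and −0.12 in HL-60, THP-1 and U937.

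Interferon genes were higher in 11 of 38 cases and lower in 1, and in 12 and 1 adjusted over the list alone. Of 20 p53 targets 4 were higher and 1 lower, with 6 and 1 adjusted over the list alone, and of 22 apoptosis regulators 9 were higher and 3 lower, with 10 and 3. Of 24 cholesterol synthesis genes 6 were higher and 0 lower, with 6 and 0 adjusted over the list alone. Their medians were 0.04, 0.07, 0.04 and 0.07, and the camera calls (adjusted p = 3.0e-04, 0.0189, 0.0189 and 0.0189) were all lost, at adjusted p = 0.148, 0.139, 0.0844 and 0.684 with an estimated correlation. Within columns 1 to 6 and 7 to 11 the medians were 0.04 and 0.06 for interferon genes, 0.04 and 0.09 for p53 targets, 0.06 and 0.03 for apoptosis regulators and 0.11 and 0.05 for cholesterol synthesis. The apoptosis call was lost when blocked on plate columns (adjusted p = 0.0535), and it and the cholesterol call were lost within columns 7 to 11 (0.266 and 0.266). NRF2 targets, not called in the pooled fit (0.175), were called higher when blocked (0.0415, lost at adjusted p = 0.154 with an estimated correlation), and ATF4 targets (0.696) were called lower within columns 1 to 6 (0.00298, lost at 0.698). Blocked on plate columns with an estimated correlation, mature myeloid (adjusted p = 0.00388) and MYC genes (0.00194) held and lysosome genes did not (0.112), and within columns alone none of these held (at least 0.355, 0.230 and 0.160).

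Against the shared controls, 118 genes were higher and 71 lower with both targets, and 44 were called in opposite directions, where independent lists would share 23.4 and 19.2. Those values make no allowance for the shared controls, so the excess over them is not read as agreement between the targets. IL1RAP was one of the opposite ones, at 0.34 and 0.23 with hairpins 5 and 6 and −0.40 and −0.48 with B-1 and B-2. Over genes the GSK3A and GSK3B changes had r = 0.318, below the 0.572 that shared controls gave in simulations with no change. Their covariance was 0.00298 against a simulated 0.00141. With the controls split between the targets the median r was 0.176 (−0.0861 to 0.284).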

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

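The tests of plate position, of control imbalance over plate columns, of the MOLM-14 part of RNA degradation and of single-hairpin effects as the whole cause, and all counts over other splits of the arrays, were chosen after the results were seen. The other tests of explanations were written before their values were known.

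The response to the GSK3A hairpins differed between the 4 lines for 953 genes and that to the GSK3B hairpins for 26 genes, by an interaction test (limma). With the GSK3A hairpins CD14 differed with adjusted p = 1.3e-09 (1.21 in HL-60 and 0.09, −0.00 and 0.03 in THP-1, MOLM-14 and U937). TNFAIP6, which encodes a hyaluronan-binding protein of inflammation, differed with adjusted p = 1.7e-09 (−1.08 in HL-60 and −0.01, −0.02 and −0.00 in the others). ZMAT3, a p53 target, differed with adjusted p = 3.2e-09 (1.38 in MOLM-14 and 0.07, −0.15 and 0.10 in HL-60, THP-1 and U937). CASP8AP2 also had adjusted p = 3.2e-09 (−0.84 in MOLM-14 and 0.18, −0.23 and −0.16 in HL-60, THP-1 and U937), and CRISPLD2 had 1.2e-08 (0.79 in HL-60).

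With the GSK3B hairpins MPO differed between lines with adjusted p = 2.9e-06 (−1.42 in MOLM-14). PRG2, an eosinophil granule gene, also had 2.9e-06 (0.85 in HL-60), and RBM47 had 5.3e-07 (−0.45 in HL-60 and 0.28 in MOLM-14). LIN7A had 4.3e-05 (0.42 in HL-60 and −0.22 in THP-1), and CEBPE, a transcription factor of granulocytes, had 0.00101 (0.48 in HL-60). The probe sets that name no gene, which the comparisons of genes do not use, held 185 calls with the GSK3A hairpins (89 higher, 96 lower) and 38 with the GSK3B hairpins (19 higher, 19 lower) of 1923 (limma).

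Arrays of MOLM-14 and U937 split by plate columns: between columns 7 to 11 and columns 1 to 6, 3176 genes differed in MOLM-14 and 4312 in U937, and 0 in HL-60 and 0 in THP-1 (limma, with an unadjusted p under 0.05 for 816 and 775). The effects of both lines had r = −0.126 over genes. The highest share of genes with such an effect in HL-60 and THP-1, which lie in the same columns, was 0 percent, which argues against a plate position shared by all lines. The log2 ratio of 3' to 5' signal of the actin and GAPDH control probe sets rose by 1.10 ± 0.153 (SE) in MOLM-14, as a difference in RNA degradation would give, while in U937 it was 0.231 ± 0.0229. That lies under the bound of 0.25 written beforehand, which counts against degradation as the cause in both lines. The bound made no allowance for the standard error, and with it the U937 value reaches past 0.25, so it is left open. No biological explanation was tested, and separate cultures or days of infection may also underlie the split, since the labels give neither.

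More genes changed with GSK3A than with GSK3B hairpins, 2560 against 404. The median residual SD of GSK3A arrays was 1.04 times that of GSK3B arrays, which argues against a larger spread or power. With split controls hairpins 5 and 6 kept r = 0.383 (0.273 to 0.427), which argues against effects private to each hairpin as the whole cause. With B-1, hairpin 5 had r = 0.331 (0.125 to 0.401) and hairpin 6 had 0.201 (−0.0310 to 0.302). With B-2 they had −0.0526 (−0.197 to −0.0100) and 0.0492 (−0.136 to 0.0978). Effects that the GSK3A hairpins share with B-1 are therefore not excluded. Whether single-hairpin effects make part of the difference stays open, since the differences of hairpin 5 from B-1 and of hairpin 6 from B-2, which share no array, had r = 0.292, between the bounds of 0.1 and 0.3. A larger role of GSK3A in these cells is 1 hypothesis, and it is untested here because the GSK3A transcript moved by only −0.09 and protein levels were not analysed here.

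The mature myeloid list was higher with GSK3A hairpins. Hairpin 6 on its own gave a median of 0.13 (0.132), which argues against hairpin 5 alone, and the median with plate columns as a block was 0.25 (0.253), which argues against the imbalance of controls over columns. Genes high in another line and near the floor in U937 had a highest median change of 0.00869, which argues against cells of another line in the U937 cultures. GSK3B hairpin B-1 gave the same median of 0.13 (camera, adjusted p = 6.6e-09, and 0.0101 with an estimated correlation) and B-2 gave −0.06, so a response that is not specific to GSK3A stays open, as do off-target effects of both GSK3A hairpins. A shift toward more mature myeloid expression after GSK3A suppression is therefore only 1 hypothesis, found and tested on the same arrays.

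Other splits of the same arrays were fitted with limma, with the hairpins of a target as 1 group, so the real counts differ from those in the comparisons. Of 35 splits of the 7 arrays of a line, 1, the real one, gave as many genes with GSK3A hairpins in HL-60 (756; highest other 0), in THP-1 (125; 0) and in MOLM-14 (384; 173). The same held with GSK3B hairpins in HL-60 (10; 0). Other groupings of single arrays did not reach these counts. The splits separate the replicates of a hairpin, so an effect of a single hairpin outside its target would exceed them too. With GSK3B hairpins in THP-1 1 of 35 splits, the real one, gave as many (1; 0), but a single gene, which the targeted GSK3B itself can supply, says nothing about a wider response. For GSK3A in U937 2 of 35 splits gave as many (real 3; highest other 1893), for GSK3B in MOLM-14 2 (real 2; 1464) and for GSK3B in U937 all 35 (real 0, with 694 at an unadjusted p under 0.05 in the fit of all arrays; 2753), so these splits cannot exclude chance there. In each of these, and in MOLM-14 with GSK3A, the highest other split was the one that follows plate columns, which points to a structure of the samples. With plate columns as a block the counts were 1941, 823 and 218, and 3391 for GSK3A in MOLM-14. A real count of 0 fixes the outcome in advance, so the splits say nothing about GSK3B in U937, where GSK3B itself changed by −1.58 ± 0.09. For GSK3A in U937 the lysosome and mature myeloid lists were called with an estimated correlation (camera, adjusted p = 0.00108 and 0.00805).

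Of 100 splits drawn within lines, 1, the real one, gave as many genes for the mean of GSK3A hairpins (1876; highest other 455), for both GSK3A hairpins (926; 40) and for the difference between targets (1617; 106). Other groupings of single arrays did not reach these counts, but such splits cannot tell an effect of the target from effects of its single hairpins. For both GSK3B hairpins 2 of 100 did (72; 483), and the other split had far more genes than the real one, so chance is not taken as excluded there. It cannot be excluded in this way for the mean of GSK3B hairpins (9 of 100; real 114; highest other 981), the differences between lines with GSK3A hairpins (7; 308; 1311) and those with GSK3B hairpins (18; 7; 2112). Splits with several times the real count again point to a structure of the samples. With splits drawn within plate columns and columns as a block, 1 of 100 gave as many for the mean of GSK3A hairpins (2432; 562), both GSK3A hairpins (1695; 58), the differences between lines with GSK3A hairpins (887; 438), the mean of GSK3B hairpins (344; 56), both GSK3B hairpins (361; 6) and the difference between targets (2268; 1627). Other groupings of single arrays within columns did not reach these counts, though for the difference between targets 1 came to 1627 against 2268. These splits also separate the replicates of a hairpin, so effects of single hairpins would exceed them too. For the differences between lines with GSK3B hairpins it was 4 of 100 (21; 56), and since other splits reached the real count, chance is not taken as excluded there.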

How the results depend on the processing

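The alternatives without a pseudocount, without quantile normalization, with controls 1 and 2 averaged, and within plate columns 1 to 6 or 7 to 11 alone were chosen after seeing the data. No count and no named gene result that had passed the test reversed its direction, nor did a list result with all arrays. Within columns, the GSK3B cell cycle list, not called with all arrays (−0.01, adjusted p = 0.354), was called lower in columns 1 to 6 (−0.06, 0.0017) and higher in columns 7 to 11 (0.08, 0.0143). Median scaling, cyclic loess and no quantile normalization each left every count within 1.5 times, and each kept 276 of 280 named gene results on their side of the threshold. For the 6 genes of GSK3B in THP-1 the share that rose went from 2 of 6 to 3 of 7 with median scaling. GSK3B with its hairpins stayed past the threshold throughout. Unless a clause below names it, the cause was not tested.

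The GSK3A transcript with GSK3A hairpins (−0.09, adjusted p = 0.0176) was no longer past the threshold with trended and robust variances (−0.0895, 0.0601), a replicate block (−0.0669, 0.112), a random block (−0.0895, 0.110), without HL-60 (−0.0510, 0.376), in columns 1 to 6 (−0.0830, 0.282), in columns 7 to 11 (−0.12, 0.462) and on its other probe set (−0.0818, 0.0908). Over the alternatives its adjusted p ran from 0.00381 to 0.462.

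With plate columns as a block, which removes the column effect from the residual, the counts were 4041 for GSK3A over the lines, 1230 for GSK3B, 4106 between targets, 1784 and 292 for both hairpins of GSK3A and of GSK3B, 2418, 909, 3391 and 1941 for GSK3A in HL-60, THP-1, MOLM-14 and U937, 484, 33, 823 and 218 for GSK3B, and 3033 and 158 for differences between lines. With a replicate block they were 1039 for GSK3B over the lines, 1562 and 257 for both hairpins, 2909 and 2255 for GSK3A in MOLM-14 and U937, 187, 16, 977 and 756 for GSK3B in the 4 lines, and 2368 and 169 between lines. Replicate numbers do not pair the arrays: hairpin arrays of the same number had residual correlations of 0.561 to 0.753 in MOLM-14 and 0.762 to 0.7997 in U937, but control 2 lay at −0.587 to −0.427 and −0.707 to −0.644 with number 2.

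Fits within columns 1 to 6 used fewer arrays. They also took the hairpins of a target as 1 group, so differences between hairpins entered the spread. For GSK3A, for GSK3B and between targets they gave 1405, 27 and 938. In the lines they gave 119, 23, 1161 and 147 for GSK3A and 5, 2, 15 and 2 for GSK3B, with 230 and 5 between lines. Columns 7 to 11, with 1 control array per line, gave 42, 2 and 387, 4, 4, 52 and 2, 0, 0, 1 and 0, and 0 and 0 (limma, with 439, 173, 225, 599 and 202 genes at an unadjusted p under 0.05 where the count was 0). With controls 1 and 2 averaged the counts were 183 for GSK3B, 32 for both GSK3B hairpins, 720, 90, 1258 and 352 for GSK3A in the lines, 60, 44 and 4 for GSK3B in HL-60, MOLM-14 and U937, and 404 and 7 between lines. A random block for cell line and construct (correlation 0.140) gave 1265, 22 and 1473 over the lines.

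Without HL-60 the counts were 1593, 126 and 1710, and without THP-1 GSK3B had 245. A fold of at least 1.5, which is a stricter rule, left 38, 3 and 44. With only the arrays of the groups compared GSK3A had 2330, 781, 930 and 15 in the lines, and GSK3B 322 in HL-60, 1 in MOLM-14 and 1 in U937. Without a pseudocount GSK3A had 127 in THP-1 and GSK3B 2 in THP-1, 7 in U937 and 8 between lines. Without dim genes GSK3B had 3, 12 and 13 there. Every probe set gave GSK3B 11 in THP-1, and trended and robust variances 6 in U937.

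Leaving out 1 array, with a lone array of a group assumed to vary like the other groups, gave 2313 to 2806 for GSK3A, 315 to 514 for GSK3B, 2445 to 2815 between targets, 797 to 1103 for both GSK3A hairpins and 46 to 95 for both GSK3B hairpins (95 without U937 control 3). GSK3A had 807 to 877 in HL-60, 1387 to 1928 in MOLM-14 and 400 to 1200 in U937 (400 without control 2, 416 without control 1). In THP-1 it had 121 to 195, with 127, 121 and 143 without controls 1, 2 and 3, 155 and 144 without replicates 1 and 2 of hairpin 5, and 145 without replicate 2 of hairpin 6. GSK3B had 74 to 91 in HL-60 (74 without control 1), 3 to 11 in THP-1 (3 without control 1, 11 without replicate 1 of B-2), 69 to 492 in MOLM-14 (69 and 70 without controls 1 and 2, 116 without replicate 2 of B-1, 492 without replicate 1 of B-2) and 4 to 130 in U937 (4 without control 1 and 4 without control 2, 130 without control 3, 17 without replicate 2 of B-1). Differences between lines ranged from 718 to 1189 for GSK3A and from 15 to 38 for GSK3B (15 without HL-60 control 1 and 15 without control 3). The GSK3B count in HL-60 fell from 120 and the GSK3A counts in HL-60 and THP-1 from 1097 and 245 with fewer arrays.

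Of the 280 named gene results, 280 stayed on their side of the threshold with the column block, 274 with the replicate block, 275 with trended and robust variances, 270 without a pseudocount, 261 of 264 without dim genes, 259 with only the groups compared, 248 with controls averaged, 147 in columns 1 to 6 and 57 in columns 7 to 11. Of the 233 over the lines, 156 did with the random block, 177 without HL-60, 214 without THP-1, 193 without MOLM-14 and 222 without U937. Leave-one-out values were the same in 6997 of 7217 cases, weaker in 218 and stronger in 2. Of 66 list results, 57 stayed with an estimated correlation, 56 with fry, 60 with the column block (5 gained a call and 1 lost it), 63 with the replicate block, 63 without dim genes, 65 without a pseudocount and 66 with cyclic loess. Signal over background limits dim genes: array medians were 18.95 to 22.9, near the pseudocount of 16, so log2 changes there are understated.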

Other observations

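The values here of single hairpins and of plate columns were chosen after the results were seen, and no explanation was tested for them.

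A few genes moved alike with all 4 hairpins. DYNLRB1, a light chain of dynein, rose by log2 0.81 and 0.68 with GSK3A hairpins 5 and 6 and by 0.61 and 0.70 with GSK3B hairpins B-1 and B-2 (SE 0.04). HSD17B10, a mitochondrial dehydrogenase, rose by 0.69, 0.61, 0.49 and 0.64 (SE 0.07). The control arrays are shared by these comparisons, so a value of the controls that differs from all hairpins gives the same picture. In MOLM-14 the myeloperoxidase gene MPO went from a normalized intensity of 109 ± 26.6 (SD, n = 3) in controls to 32.7 and 35.7 with hairpins 5 and 6 and to 41.2 and 21.1 with B-1 and B-2.

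Other genes fell mostly with a single hairpin. CNN2, an actin-binding calponin, changed by −1.53 ± 0.04 with hairpin 5 and −0.09 ± 0.04 (adjusted p = 0.20) with hairpin 6 (limma). RRN3, a factor of ribosomal RNA transcription, changed by −0.23 with hairpin 5 and −1.05 with hairpin 6. RNF170, a ubiquitin ligase, changed by 0.03 with B-1 and −0.84 with B-2. CD14 in HL-60 had a normalized intensity of 346 with B-1 and 147 with B-2, against 263 ± 8.94 (SD, n = 3) in controls.

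Plate columns 7 to 11 differed from 1 to 6 in HMOX1, a heme oxygenase, at log2 1.61 in MOLM-14 and −2.42 in U937, and in EGR1, an immediate early gene, at −1.31 and 3.15. The calprotectin gene S100A8 differed by 1.51 in MOLM-14 and −1.90 in U937. Replicates in different columns differed with a spread of 0.219 to 0.305 in MOLM-14 and 0.235 to 0.286 in U937, and of 0.0977 to 0.132 in HL-60 and THP-1. Over genes the GSK3A changes of the lines had r from 0.196 (THP-1 and MOLM-14) to 0.573 (HL-60 and U937).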
